A study of Mus musculus with 10 samples.

How the data were processed

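Droplet single-cell libraries of mouse lymph nodes, made with the 10x Genomics 3' kit, were the input. The authors deposited them as UMI counts per gene or antibody and cell barcode, without normalization, made with Cell Ranger 7.0 on mm10 per the submitters' processing notes. The gene annotation, the cell calling and the intron setting are not given in the sources used here. In each of the 5 gene libraries the count table listed 32285 genes, and every barcode held at least 500 gene UMIs. The antibody counts deposited beside them covered 4 hashtags in the stromal library, 3 in each of the other 2 hashtagged libraries and 24 surface antibodies in each atlas. A hashtag was tied to a condition by the name that the deposited feature table gives it. No hashtag names poly(I:C), and the T cell library has none for LPS, so neither was analysed here.

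Barcodes numbered 3507 in the stromal library, 7823 in the myeloid and stromal library, 8117 in the T cell library, 11690 in the axillary atlas and 25196 in the mediastinal atlas. Cells needed at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs, which 2535, 6526, 7755, 11503 and 25148 met. A hashtag was called where its count was at least 10 and at least 3 times the next one. Droplets with a second hashtag at 10 or more were removed as doublets (7.22%, 17% and 6.98% of the hashtagged libraries), and 2, 4 and 4 had no hashtag. Doublets of 1 condition carry a single hashtag and stayed in. In the atlases scrublet, run through scanpy 1.11.5, marked 7.81% of axillary and 0 mediastinal cells, so it did not work on the mediastinal atlas. Cells used numbered 2350, 5412, 7210, 10605 and 25148.

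Each library was clustered by itself, on log-normalised counts of 2000 variable genes without immunoglobulin and T cell receptor segments, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, seed 1). A cluster was called a cell class from fixed marker lists where its mean standardised marker score reached 0.7, at least 3 markers were present in 10% of its cells and no second lineage reached 0.45 of that score. T cell names also had conditions on Cd4, Cd8a, Trdc, Foxp3 and Cd3e. A cluster whose 10 leading genes held more markers of another class, or whose median UMIs lay far under its library's with no marker of its own leading, stayed unnamed. The markers were fixed before the data were examined, and the scoring rule was set on the data.

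Counts were summed per library, condition and class. Fibroblast-like sums of 3 conditions in 2 libraries were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with filterByExpr, TMM scaling and the library as a block, since conditions of a library were prepared together per the labels. The 12821 genes tested had a biological coefficient of variation of 0.140 and 2 residual degrees of freedom. An adjusted p (Benjamini-Hochberg) under 0.05 counted as passing. Of the 27 fixed gene lists, members were also adjusted over the list alone, and camera of limma 3.58.1 was run with a preset and an estimated correlation. DESeq2 1.42.0 was the other tool run. On simulated counts for 4T1 over naive (12557 genes) edgeR recovered 79% of log2 changes of 1 and 99% of those of 2, with 3 false calls, and DESeq2 60% and 99%, with 1.

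Other classes were compared on 1 sum per condition, without a test, as log2 ratios of CPM. CPM is the UMIs of a gene over all UMIs of the sum at a fixed scale. The ratios carry exact conditional binomial 95% intervals, which cover counting error only. A gene with no UMI in a group was set at a floor of 3 UMIs per group and its ratio given as a bound. On simulated counts of monocytes (9123 genes) 95.4% of intervals held an unchanged ratio, 95.8% a log2 change of 1 and 95.5% one of 2. For a gene list, members with at least 50 UMIs in the higher group counted as measured, the median was ranked among 10000 random lists matched on expression, and its interval came from 1000 Poisson draws of the counts. Where 2 sums differ in size, the minimum of 50 UMIs favours members higher in the larger sum. Shared naive sums were judged against simulated unchanged groups. Coordinates came from the GENCODE annotation of GRCm38, the assembly that mm10 names. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

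Comparisons, markers, gene lists and the rule for named genes were set before the data were examined. The rule took the 12 highest and the 12 lowest log2 ratios per comparison, among genes with at least 50 UMIs in the higher group and an interval that excludes 0. In the fibroblast test it took those that passed with the same sign in both libraries. From each list described it took the 2 to 4 members with the largest ratio, and wherever measured 11 genes: Tlr4, Cd14, Ly96, Ccl2, Ccl7, Ccl19, Ccl21a, Cxcl13, Cxcl12, Ccr2 and Ly6c2. Segment, haemoglobin, mitochondrial and unnamed-locus genes were counted but not named outside the lists. Of the 936 genes the rule gave, 249 had over 50% of their UMIs in 1 cell and were left unnamed, a choice made after the values were seen, and the text names a part of the rest. Some genes that the rule gave are not reported here. Alternatives numbered 43 planned and 11 added after the data were seen. They changed the UMI minimum, the mitochondrial limit, doublets, Leiden resolution, scaling, gene filter, depth, tool, block, library, hashtag ratio and class names. LPS and blood endothelial comparisons and the T cell clusters compared by number were chosen after the data were seen.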

Results

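Axillary lymph nodes of 8-week-old female BALB/c mice were profiled by droplet single-cell RNA sequencing after orthotopic growth of 4T1 or 67NR cells, 2 mouse mammary carcinoma lines of which 4T1 metastasises and 67NR does not, and in untreated (naive) mice. Tumours had grown for 18 days, to 500 mm3. By its title the series concerns a fibroblast and monocyte axis that depends on Tlr4, the receptor for bacterial lipopolysaccharide (LPS). The series held 10 samples, made of 5 gene libraries, each with a matched antibody library. The stromal library held 4 hashtagged conditions (4T1, 67NR, LPS for 72 hours, naive), and the myeloid and stromal library and the T cell library held 3 each (4T1, 67NR, naive). The other 2 gene libraries were atlases of the naive axillary and mediastinal nodes, with 24 surface antibodies. Gene counts totalled 36622159 UMIs in the stromal library, 94930947 in the myeloid and stromal library, 121022621 in the T cell library, 87408477 in the axillary atlas and 67290580 in the mediastinal atlas. Median UMIs per cell used were 12899, 10802.5, 10930, 6430 and 2272, in the same order. Each condition carried 1 hashtag per library, and the labels give at least 3 mice per condition but no map from cells to mice. Replicate sums thus needed a class in 2 hashtagged libraries, and only fibroblasts were tested on them. The stromal library also held a few migratory dendritic-like cells (6 in 4T1, 11 in 67NR and 12 in naive nodes), which were not compared. B-like cells stood in 2 hashtagged libraries and were not compared between conditions. Nothing in the labels says that the 2 libraries with fibroblasts came from separate mice, and p-values then measure only the spread between these libraries, which may be technical. All other comparisons used 1 sum per condition, with no replicate check. The ranges that follow their log2 ratios are exact 95% intervals that cover counting error only (list medians: intervals from resampled counts).

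Clusters were named from fixed markers, and shares of cells carry exact Clopper-Pearson 95% intervals. In the stromal library the fibroblast-like class made up 1050 of 2350 cells (44.7%, 42.7 to 46.7%), the blood endothelial-like class 702 of 2350 cells (29.9%, 28.0 to 31.8%) and the lymphatic endothelial-like class 174 of 2350 cells (7.40%, 6.38 to 8.54%). In the myeloid and stromal library, neutrophil-like cells were 1191 of 5412 cells (22%, 20.9 to 23.1%), monocyte-like cells 1024 of 5412 cells (18.9%, 17.9 to 20%) and fibroblast-like cells 702 of 5412 cells (13%, 12.1 to 13.9%). Other settings moved these shares beyond their intervals: neutrophil-like cells made up 33.8% with at least 1000 UMIs per cell, 34.7% with at most 5% mitochondrial UMIs and 34.5% with a hashtag ratio of 10, where fibroblast-like cells made up 7.23%. Monocyte-like cells numbered 547 in 4T1, 235 in 67NR and 242 in naive nodes, and migratory dendritic-like cells 93, 78 and 316. In the T cell library CD8 T-like cells were 1919 of 7210 cells (26.6%, 25.6 to 27.7%), regulatory T-like cells 1525 of 7210 cells (21.2%, 20.2 to 22.1%) and CD4 T-like cells 1219 of 7210 cells (16.9%, 16.0 to 17.8%), and with wide class names CD8 T-like cells were 40.8%. NK-like cells were 2067 of 10605 cells (19.5%, 18.7 to 20.3%) of the axillary atlas and B-like cells 1527 of 10605 cells (14.4%, 13.7 to 15.1%). In the shallow mediastinal atlas 24708 of 25148 cells stayed unnamed. The sort set these shares, and they describe the libraries rather than the nodes. Clusters of the hashtagged libraries that stayed unnamed held 53 of 422 cells (12.6%, 9.55 to 16.1%) of 4T1, 274 of 908 cells (30.2%, 27.2 to 33.3%) of 67NR and 13 of 410 cells (3.17%, 1.70 to 5.36%) of naive nodes in the stromal library. They held 129 of 1501 cells (8.59%, 7.23 to 10.1%), 271 of 1731 cells (15.7%, 14.0 to 17.5%) and 525 of 2180 cells (24.1%, 22.3 to 25.9%) in the myeloid and stromal library. Among them was a stromal cluster led by Smpd3 and Fn1, with 31 cells in 4T1, 218 in 67NR, 9 after LPS and 3 in naive nodes. It scored as a fibroblast on the fixed markers, but its leading genes held 1 marker of monocytes and 0 of fibroblasts, so the fibroblast tests leave it out. Wide class names called it fibroblast-like, and that class then held 62.7% of the 67NR cells of the library against 38.7%, and 62.7% at Leiden resolution 2. Another was a low-UMI cluster led by Hcar2, with 32, 202 and 400.

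The first comparison asked how fibroblasts of nodes draining a 4T1 tumour differed from naive ones. Ptx3, which encodes the soluble pattern recognition protein pentraxin 3, rose by a log2 fold of 1.68 ± 0.14 (SE, 2 libraries), and Timp1, an inhibitor of matrix metalloproteinases, by 1.93 ± 0.29 (adjusted p = 0.00898 and 0.0400 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tnfsf8 rose by 2.15, Serpina10 by 1.98, Chl1 by 1.90, Serpina3g by 1.85 and Nrep by 1.67. The methyltransferase gene Inmt fell, at -1.54 ± 0.21, as did Fst, the activin antagonist follistatin, at -1.33 ± 0.13 (adjusted p = 0.0358 and 0.0236, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Other genes that fell were Frmpd4 (-2.60), Wdr95 (-2.45), Stc1 (-1.54), Igfbp3 (-1.44), Epha4 (-1.43), Ano1 (-1.37), Col23a1 (-1.21), Fmo2 (-1.18) and Hsph1 (-0.96). Larger folds of Csf3 (4.19), Dmkn (3.41), Cxcl3 (2.40) and Ccl5 (-2.61) rested on the myeloid and stromal library, with under 10 UMIs in both the 4T1 and the naive fibroblasts of the stromal library. In the former library the 5% of fibroblast droplets with the most UMIs of each held 100, 100, 96.2 and 84.9% of them. Of 12821 genes, 49 rose and 23 fell, 63 of the 72 had the same sign in the stromal library alone, and 57 had at least 10 UMIs in the higher group in each library (42 higher, 15 lower). The stromal library is part of the test, so a shared sign there is no replication. With a hashtag ratio of 10, chosen after the data were seen, 15 genes passed, and in an edgeR fit with no replicate block (without the library as a block) 0 passed, with 437 at an unadjusted p under 0.05, where DESeq2 with the block called 105. Fewer genes passed with at most 5% mitochondrial UMIs (38), with cells thinned to 1000 UMIs (38) and in the clusters led by Ccl19 and Ccl21a alone (17). Of the 72 calls these kept 37, 21 and 7, and 2 turned sign in those clusters. The hashtag ratio of 10 kept 11, with 1 turned. More passed at Leiden resolution 2 (135, with 60 of the 72 kept) and with wide class names (129, with 59 kept). Without a gene filter 713 passed, 383 higher and 330 lower, so that 53.7% were higher, against 68.1% with it.

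In fibroblasts of nodes draining a 67NR tumour, Tnfsf8 rose by 2.68 ± 0.31, the collagen gene Col8a1 by 3.29 ± 0.43, Tnc, which encodes the matrix glycoprotein tenascin C, by 3.07 ± 0.52 and Cxcl5, a chemokine that attracts neutrophils, by 2.72 ± 0.39 (adjusted p = 0.0201, 0.0234, 0.0485 and 0.0282, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Csf3, the granulocyte growth factor G-CSF, rose by 4.58 ± 0.52, with 15 UMIs in the 67NR fibroblasts of the stromal library against 188 in the other, where 35 of 702 fibroblasts of all conditions held the 313 Csf3 UMIs. Fgf23 (3.81), Syt13 (2.98), Thbs4 (2.31) and Alk (2.24) also rose. Inmt again fell, at -1.65 ± 0.21, and so did Frmpd4 (-2.35), Spata7 (-1.69), Fst (-1.27), the Wnt agonist gene Rspo3 (-1.27), Id2 (-1.20), Fmo2 (-1.14) and Txnip (-1.0). Csf2 (4.48), Pkib (2.78) and Ccr7 (-2.19) passed with at most 1 UMI per condition in the stromal library, and 100, 93.4 and 90.2% of their UMIs in the other lay in 5% of the fibroblast droplets. Plasma cell transcripts stood beside these: Igkc had 28449 UMIs in the 67NR fibroblasts of the stromal library, 51.3% of them in 1 cell, against 13 in naive ones, and 367 against 157 in the other library (adjusted p = 0.283, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over the other settings this p ran from 5.95e-166 to 1.00, and Igkc passed in DESeq2 (0.0321), with cells thinned to 1000 UMIs (0.00491) and without a gene filter. In all, 68 genes rose and 11 fell. The same sign in the stromal library alone was found for 79 of the 79, but that library is part of the test. At least 10 UMIs in the higher group in each library were found for 75 (65 higher, 10 lower). The edgeR fit with no replicate block passed 0 genes, with 406 at an unadjusted p under 0.05 and 136 called by DESeq2 with the block, and Leiden resolution 2 gave 339 calls, 66.1% of them higher against 86.1%. Wide class names gave 340, no gene filter 759 (69.4% higher), at least 1000 UMIs per cell 122 and the clusters led by Ccl19 and Ccl21a alone 40. Those clusters kept 13 of the 79 calls, and 3 turned sign. A hashtag ratio of 10 gave 86, with 44 of the 79 kept and 1 turned.

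Among the gene lists, collagen and matrix genes rose in both tumour conditions: 6 of 28 measured members rose in 4T1 and 6 in 67NR over all genes tested, and 19 and 18 rose when adjusted over the list alone, with 1 lower each. Col3a1 rose by 1.16 in 4T1 and 0.91 in 67NR, Sparc by 0.89 and 0.90, and Col6a2 by 0.86 and 0.90. Postn, which encodes periostin, rose by 1.66 in 67NR and stood at 1.25 in 4T1 without passing. The list's camera call with a preset correlation had adjusted p = 6.76e-20 and 9.77e-18 (limma's camera, Benjamini-Hochberg), and adjusted p = 0.461 and 0.252 with an estimated correlation. Of 5 measured neutrophil-attracting chemokines, 2 rose in 4T1 and 4 in 67NR (4 and 5 adjusted over the list alone). Camera gave adjusted p = 0.461 and 0.252 with an estimated correlation. The 2 of 4T1 were Csf3 and Cxcl3, with under 10 UMIs in the 4T1 and naive fibroblasts of the stromal library. In the other library 5% of the fibroblast droplets held 100 and 96.2% of their UMIs. Cxcl2 stood at 1.21 and 1.69, without passing over all genes in 4T1. Of 10 homeostatic stromal factors 2 and 3 rose (3 and 4 adjusted over the list alone, with 1 and 0 lower), among them the alarmin gene Il33 at 1.38 and 1.52 (adjusted p = 0.461 and 0.252 with an estimated correlation). Of 21 NF-kB early targets 5 rose in 67NR, with Nfkb1 (0.94), Vcam1 (0.92) and Ier3 (1.0), and 0 in 4T1, where 10 stood at an unadjusted p under 0.05 in edgeR and 4 rose in DESeq2. Adjusted over the list alone 6 rose and 2 fell in 4T1, and 7 rose and 1 fell in 67NR (adjusted p = 0.488 and 0.252 with an estimated correlation). Of 7 contractile genes 0 passed edgeR's test over all genes, with 4 and 5 at an unadjusted p under 0.05 and 1 and 2 higher in DESeq2. Adjusted over the list alone 2 and 4 of them rose, and 0 and 1 fell (adjusted p = 0.488 and 0.382 with an estimated correlation), and Tagln stood at 1.05 and 1.10. Of 19 type I interferon response genes 0 passed edgeR's test, with medians of -0.38 and -0.53, 2 and 10 at an unadjusted p under 0.05, 0 in DESeq2, and 0 and 1 lower adjusted over the list alone (adjusted p = 0.614 and 0.564 with an estimated correlation). In the clusters led by Ccl19 and Ccl21a alone, chosen after the data were seen, the interferon medians were 0.45 and 0.40, the collagen and matrix ones 0.60 and 0.28, against 0.66 and 0.51 in all fibroblasts, and the homeostatic ones -0.11 and -0.29, against 0.58 and 0.76. The NF-kB medians there were 0.72 and 1.0, against 0.12 and 0.30, and the contractile one of 4T1 0.87, against 0.53. Col6a2 in 67NR turned to -0.011 there. With a hashtag ratio of 10 the 67NR interferon median was -0.82 and the 4T1 homeostatic one 0.14. After thinning of cells to 1000 UMIs the contractile medians were 0.068 and 0.050, against 0.53 and 0.69, and the 67NR NF-kB one 0.50. At Leiden resolution 2 the 67NR homeostatic median was 0.34 and the contractile one 0.23, and with wide class names 0.34 and 0.24. Dissociation stress genes had medians of -0.35 and -0.09, and genes of damaged cells 0.20 and 0.10. In the clusters led by Ccl19 and Ccl21a these turned to 0.17 and 0.66 and to -0.010 and -0.22.

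Tlr4 in fibroblasts stood at 0.07 ± 0.16 in 4T1 and 0.00 ± 0.15 in 67NR over naive (SE, 2 libraries; adjusted p = 0.900 and 0.993, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and its sign turned in some other settings. Of 14 TLR4 receptor and adaptor genes 0 passed edgeR's test over all genes in either condition, with 2 and 2 at an unadjusted p under 0.05, 0 in DESeq2, and 1 and 0 higher adjusted over the list alone (adjusted p = 0.614 and 0.958 with an estimated correlation). Its co-receptor gene Ly96 stood at -0.09 and 0.26 and Cd14 at 0.50 and 0.62. Ly96 in 4T1 turned to 0.017 with a hashtag ratio of 10 and to 0.73 in the clusters led by Ccl19 and Ccl21a alone. Ccl2, the main chemokine for Ccr2-bearing monocytes, rose by 1.33 ± 0.18 in 67NR and stood at 0.75 in 4T1 (adjusted p = 0.0243 and 0.143, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Ccl7 was at 1.01 and 0.76 without passing. Cxcl13 was at 1.78 in 4T1 and 0.80 in 67NR, Cxcl12 at -0.15 and 0.27, the latter turning to -0.070 at Leiden resolution 2, to -0.071 with wide class names and to -0.30 in the clusters led by Ccl19 and Ccl21a alone. Ccl21a rose by 1.05 and 1.47 and Ccl19 was at 0.30 and 0.72, both uncertain because near-identical gene copies share their reads. In those clusters alone Ccl19 turned to -0.50 and -0.28. In mm10 coordinates the named genes lie at Tlr4 (chromosome 4, 66827584 to 66930284), Ptx3 (chromosome 3, 66219910 to 66225805), Timp1 (chromosome X, 20870166 to 20874735), Inmt (chromosome 6, 55170626 to 55175043), Fst (chromosome 13, 114452290 to 114458951), Ccl2 (chromosome 11, 82035571 to 82037453) and Il33 (chromosome 19, 29925114 to 29960718), all annotated as protein-coding.

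**Figure D1:**
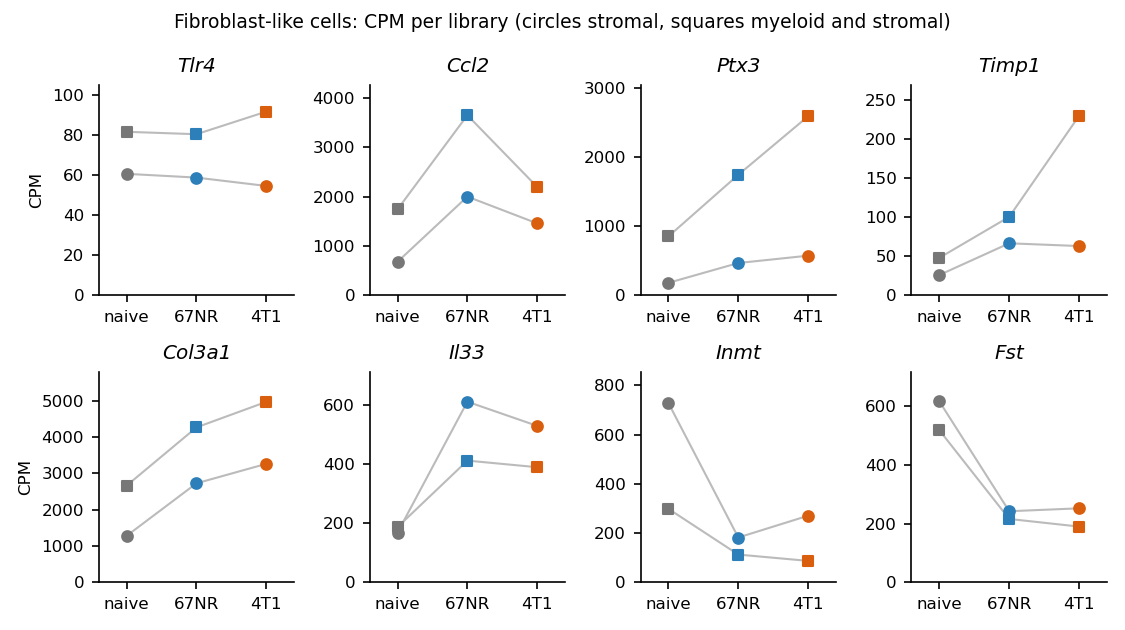
CPM of 8 genes in the summed fibroblast-like cells of each condition (horizontal axis) in the stromal library (circles) and the myeloid and stromal library (squares), 1 point per library and condition, with lines joining points of a library. Ptx3 and Col3a1 lie higher, and Inmt and Fst lower, in both tumour conditions than in naive nodes in both libraries.

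Between the tumour conditions, 3 genes passed in fibroblasts: Wfdc17 rose in 4T1 over 67NR (2.77), and Lyz1 (-4.98) and Retnlg (-3.13) fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All 3 are genes of myeloid cells with at most 1 UMI per condition in the stromal library, and 87.5, 98.1 and 86.7% of their UMIs in the other lay in 5% of the fibroblast droplets. The edgeR fit with no replicate block passed 0, with 156 at an unadjusted p under 0.05, and DESeq2 with the block called 1. Other settings called from 1 to 5 genes, and 182 without a gene filter, and in the clusters led by Ccl19 and Ccl21a alone Wfdc17 turned to -0.53 and Retnlg to 0.060. Of the genes that rose, 29 were called in both tumour conditions, against 0.260 for independent lists, and of those that fell 6, against 0.0197. Simulated unchanged groups set against the same naive sums had 0 calls in either comparison, so they give no overlap to set beside these. Fold changes of the 2 conditions correlated across genes at 0.660 (covariance 0.176), against 0.553 (0.0746) in simulated groups. A trait of the naive pools, such as their mice or handling, enters both fold changes, so the excess cannot show a shared response to the tumours.

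Monocytes of 4T1-draining nodes were compared with naive ones next, 1 sum of cells each. Saa3, which encodes an acute-phase serum amyloid protein, was higher by 2.14 (1.97 to 2.31), Stfa2 by 3.11 (2.40 to 3.94), Fcnb by 2.96 (1.80 to 4.43) and Lbp, the LPS-binding protein gene, by 2.66 (1.24 to 4.57). Ace (-3.46, -3.86 to -3.07), Myo1d (-3.36, -3.74 to -3.00), Eno3 (-3.77, -4.33 to -3.24) and Pdgfb (-3.26, -4.14 to -2.45) were lower. Alarmin and neutrophil granule genes lay above 0 in 11 of 13, with a median of 1.20 (0.92 to 1.5) at percentile 100 of random lists. Classical monocyte genes lay above 0 in 8 of 11 (median 0.49), with Vcan at 1.83 (1.72 to 1.94), Chil3 at 1.19 (1.0 to 1.39) and F13a1 at 1.02 (0.89 to 1.16). Hypoxia and glycolysis genes lay above 0 in 9 of 11 (median 0.63, Eno1 at 0.79) and proliferation genes in 12 of 13 (median 0.81, Ccnb1 at 1.85). NF-kB early targets lay below 0 in 19 of 21 (median -0.46), with Nfkbiz at -1.65 (-1.77 to -1.54), Icam1 at -1.04 (-1.20 to -0.87) and Tnf at -1.0 (-1.22 to -0.77). Interferon-gamma and MHC class II genes lay below 0 in 14 of 17 (median -0.41). Tlr4 was at 0.42 (0.29 to 0.55), Ccr2 at 0.49 (0.41 to 0.56), Ccl2 at 0.54 (0.40 to 0.70) and Ly6c2 at -0.27 (-0.33 to -0.21), and the TLR4 receptor and adaptor list had a median of 0.07. Genes of damaged cells lay above 0 in 8 of 10 (median 0.43) and dissociation stress genes below 0 in 16 of 18 (median -0.38). With a hashtag ratio of 10, chosen after the data were seen, the alarmin median was 0.61. With cells thinned to 1000 UMIs the NF-kB median was -0.27, the MHC class II one -0.27 and the TLR4 list's turned to -0.57 (and to -0.0017 with DESeq2 size factors), and the proliferation median was 2.69 with a hashtag ratio of 10 and 0.53 with at most 5% mitochondrial UMIs.

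Monocytes of 67NR-draining nodes stood apart from naive ones in other genes. Timp1 was higher by 2.92 (2.21 to 3.71) and Retnlg by 1.82 (1.66 to 1.98). Retnlg reached 15095 CPM in neutrophil-like cells of this library, which made up 36.7% of 67NR and 14.7% of naive cells. Droplets holding a monocyte and a neutrophil of the same condition were not tested for. The cell cycle genes Cdkn3 (2.03, 1.11 to 3.06), Cenpf (1.81, 1.12 to 2.55) and Ccnb2 (1.63, 1.08 to 2.21) were higher too. Chemokine genes were lower: Ccl17 at -3.22 (-4.59 to -2.09), Ccl3 at -2.54 (-2.90 to -2.19), Ccl5 at -1.87 (-2.10 to -1.65) and Ccl4 at -1.81 (-1.99 to -1.64). Ccl5 reached 8820 CPM in NK-like cells of this library, which numbered 163 in naive and 8 in 67NR nodes. Ccl17 is a fixed marker of migratory dendritic cells, which numbered 316 and 78. Ccl4 was highest in neutrophil-like cells (1100 CPM), whose share was higher in 67NR. Droplets holding a monocyte and 1 of these cells were not tested for, so the source of the falls stays open. Monocyte-attracting chemokines lay below 0 in 6 of 6 (median -1.74, -1.89 to -1.51, percentile 0). Type I interferon response genes lay below 0 in 18 of 19 (median -0.59, -0.70 to -0.53), with Ifit1 at -1.82 (-2.15 to -1.51) and Ifit3b at -2.09 (-2.73 to -1.50). Classical monocyte genes lay above 0 in 10 of 11 (median 0.26). Tlr4 was at 0.23, Ccr2 at 0.26 and Ly6c2 at 0.14. Ccl2 was at -0.27 (-0.47 to -0.07), and 0.44 with a hashtag ratio of 10, 0.24 with at most 5% mitochondrial UMIs and 0.18 (-0.76 to 1.13) with cells thinned to 1000 UMIs. In 4T1 over 67NR, Saa3 was higher by 3.84 (3.55 to 4.13), Igfbp6 by 2.76 (2.27 to 3.28), Stfa2 by 4.26 and Ccl12 by 2.77, and Lyz1 (-2.35), Ace (-2.19), Pla2g2d (-2.18) and Lpl (-2.05) were lower. There monocyte-attracting chemokines lay above 0 in 7 of 8 (median 1.15, 0.76 with at most 5% mitochondrial UMIs) and type I interferon response genes in 17 of 19 (median 0.47). Ratios of the 2 tumour conditions over naive correlated across genes at 0.702 (covariance 0.109) against 0.620 (0.0136) in simulated unchanged groups. Any trait of the single naive pool, such as its mice or handling, enters both ratios. Here and in the other classes, a value above the simulated one therefore cannot show a shared response to the tumours.

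Macrophages of the tumour conditions stood apart in interferon genes. In 4T1 over 67NR, Irf7, the interferon regulatory factor, was higher by 2.57 (2.29 to 2.86), Oasl2 by 2.27 (1.5 to 3.15), Rtp4 by 1.94 (1.37 to 2.55) and Ifit2 by 2.87 (1.44 to 4.80). The list lay above 0 in 15 of 15 (median 1.60, 1.39 to 1.75, percentile 100). Spon1 (4.0, 3.27 to 4.85), Ly6a (3.97), Kdr (3.90) and Ccl12 (3.37) were also higher, and Cd209a (-4.04, -4.92 to -3.26), Spp1 (-2.43, -2.99 to -1.91) and Il6 (-1.98) lower. MHC class I genes lay above 0 in 12 of 12 (median 0.58). Against naive nodes the interferon median was 0.63 (0.40 to 0.69) in 4T1 (13 of 17 above 0) and -0.97 (-1.19 to -0.85) in 67NR (15 of 16 below 0), with Timp1 higher in 67NR by 3.50 (2.70 to 4.42). Cluster 17, which expresses C1q genes, held 70 of the 4T1 cells, 10 of 67NR and 21 of naive, and cluster 13 held 39, 52 and 65. With a hashtag ratio of 10 the interferon median was 0.81 in 4T1 over 67NR and -0.46 in 67NR over naive, and the MHC class I median 0.34. With genes of at least 10 UMIs the 4T1 over naive interferon median was 0.37, and DESeq2 size factors shifted the log2 ratios by 0.10 in 4T1 over 67NR. Ratios of the 2 tumour conditions over naive correlated at 0.433 (covariance 0.0692), against 0.504 (0.0142) in simulated unchanged groups across genes.

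In neutrophils of 4T1 over naive nodes, Areg, which encodes the growth factor amphiregulin, was higher by 5.29 (4.44 to 6.30), Nos2, the inducible nitric oxide synthase gene, by 4.65 (3.06 to 6.95), Saa3 by 4.23 (4.01 to 4.45), Casp6 by 3.99, Wfdc17 by 3.86 and Igfbp6 by 3.76. Ifit2 (-3.53, -4.14 to -2.97), Ifit3 (-3.49, -3.98 to -3.03), Thbd (-3.75) and Thbs1 (-3.24) were lower. Type I interferon response genes lay below 0 in 17 of 18 (median -1.07, -1.27 to -0.94) in 4T1 and 17 of 18 (median -1.24, -1.35 to -1.16) in 67NR. Hypoxia and glycolysis genes lay above 0 in 9 of 10 in 4T1 (median 1.15), and alarmin and granule genes in 10 of 13 in 67NR (median 0.59, Mmp8 at 1.47, 1.34 to 1.59, S100a8 at 1.19, 1.18 to 1.20). NF-kB early targets lay below 0 in 19 of 19 in 67NR over naive (median -0.81) and above 0 in 17 of 19 in 4T1 over 67NR (median 0.62), where Saa3 was higher by 6.50 (6.24 to 6.78), Nos2 by 4.88 and Csf1 by 2.29. Different clusters held the class: cluster 10 in 4T1 (180 cells), clusters 3 and 5 in 67NR (298 and 196) and cluster 4 in naive nodes (195). The class left out the unnamed low-UMI cluster led by Hcar2 (32, 202 and 400 cells of 4T1, 67NR and naive). Naive neutrophil-like cells numbered 320, but 702 with at least 1000 UMIs per cell and 709 with at most 5% mitochondrial UMIs. Unnamed naive cells fell from 525 to 48 and 82. In 4T1 the class went from 236 to 262 and 257, and in 67NR from 635 to 819 and 825, so the naive class changed most. DESeq2 size factors shifted all log2 ratios by -0.170 in 67NR over naive and by 0.148 in 4T1 over 67NR, and the 4T1 over naive interferon median lay at -0.63 with at least 1000 UMIs per cell. There the 67NR interferon median lay at -0.79 and the alarmin and granule one at 1.13, and the NF-kB median of 4T1 over 67NR was 0.37 with a hashtag ratio of 10. Across genes the 2 ratios over naive correlated at 0.536 (covariance 0.182), against 0.662 (0.0185) in simulated unchanged groups.

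In migratory dendritic-like cells of the myeloid and stromal library, Mylk was higher in both tumour conditions, by 4.24 (3.51 to 5.05) in 4T1 and 3.71 (2.94 to 4.55) in 67NR. So was Pkib, by 3.23 (2.94 to 3.52) and 3.92 (3.64 to 4.21). In 4T1 Rerg (3.81) and Syn3 (3.73) were higher, and Csf1 (-3.63, -4.85 to -2.63) and Retnla (-3.48) lower. NF-kB early targets lay below 0 in 17 of 20 in 4T1 (median -0.79, -0.90 to -0.65) and 15 of 20 in 67NR (median -0.50), with Cxcl2 at -1.46 and Ptgs2, the inducible cyclooxygenase gene, at -1.37 in 4T1 and Il1b at -1.52 in 67NR. Maturation genes lay above 0 in 8 of 11 (median 0.22) and 9 of 11 (median 0.30), with Ccl17 at 1.42 and Cd40 at -0.53 in 4T1. In cDC2-like cells NF-kB early targets lay below 0 in 21 of 21 in 4T1 (median -0.81, Tnf at -2.69, -3.78 to -1.78, Nfkbia at -1.34) and 17 of 20 in 67NR (median -0.39). With cells thinned to 1000 UMIs the 67NR NF-kB medians were -0.78 and -0.61 and the maturation medians 0.096 and 0.093. Ratios of the 2 tumour conditions over naive correlated across genes at 0.774 in migratory dendritic-like cells (covariance 0.151), against 0.240 (0.00555) in simulated unchanged groups, and in cDC2-like cells at 0.601 (covariance 0.0788, simulated 0.251 and 0.00613).

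CD4 T-like cells of tumour-draining nodes held more transcripts of follicular helper genes. Il4 was higher by 2.41 (2.08 to 2.75) in 4T1 and 2.34 (2.01 to 2.69) in 67NR over naive, Art2b by 2.72 and 2.56, and the follicle-homing receptor gene Cxcr5 by 2.03 (1.35 to 2.76) and 1.73 (1.04 to 2.48). Follicular helper genes lay above 0 in 7 of 7 in 4T1 (median 1.02, 0.72 to 1.17, Tox2 at 1.31, Il21 at 1.20) and 6 of 6 in 67NR (median 0.33). Ccr10 (-1.62 and -2.62), Id3 (-1.66 in 4T1) and Xcl1 (-3.38 in 67NR, and 0.47, -0.78 to 1.75, with at least 1000 UMIs per cell) were lower. T helper 17 and tissue residence genes lay below 0 in 7 of 9 in 4T1 (median -0.60) and 7 of 8 in 67NR (median -0.88), and these medians turned to 0.35 and 0.05 with doublets kept. In 67NR Mnd1 (3.92), Epas1 (3.29), Myo6 (3.07) and Ifi44 (2.86) were higher; in 4T1 over 67NR Penk was at 1.91 and Myo6 at -3.14. Cluster 3, led by Sostdc1 and Il4, held 270 of the 4T1 cells, 267 of 67NR and 126 of naive, and cluster 5 held 133, 143 and 280. With doublets kept the 4T1 follicular helper median was 0.36 and with at least 1000 UMIs per cell 1.62, and the 67NR one 0.096 and 0.70. The correlation of the 2 tumour conditions across genes was 0.744 in CD4 T-like cells (covariance 0.0676), against 0.525 (0.0138) simulated, and 0.648 (covariance 0.0263, simulated 0.545 and 0.0105) in CD8 T-like and 0.732 (covariance 0.0490, simulated 0.577 and 0.0145) in regulatory T-like cells.

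In CD8 T-like cells, Ccr2 was higher by 1.36 (0.79 to 1.97) in 4T1 and 2.11 (1.57 to 2.70) in 67NR over naive, and the granzyme gene Gzma by 1.08 (0.42 to 1.77) and 1.49 (0.85 to 2.18). Activation and effector genes lay above 0 in 11 of 14 (median 0.22) and 11 of 14 (median 0.41, 0.29 to 0.51), with Gzmb at 1.01 and Ccl4 at 1.51 in 67NR and Ifng at -0.63 in 4T1. Gpr55 (2.10) and Lgals3 (1.57) were higher and Pkd2l2 (-1.83) lower in 4T1, and G0s2 (1.94) higher and Csrp2 (-1.52) lower in 67NR. With wide class names, chosen after the data were seen, the 67NR activation median was 0.10, the 4T1 one 0.12, and Gzma in 67NR turned to -0.97 (-1.24 to -0.70). In regulatory T-like cells, Gzmb was higher by 1.70 (1.39 to 2.02) and Il1rn by 1.89 (0.94 to 2.98) in 4T1, and Klrg1, a receptor of differentiated T cells, by 1.58 (1.31 to 1.86), Rsad2 by 2.44 (1.29 to 3.82) and Nckap5 by 2.65 in 67NR. Wnt10a (-2.14 and -2.13, the latter at 0.11, -2.45 to 2.88, with cells thinned to 1000 UMIs), the costimulatory gene Cd86 (-1.25, -1.50 to -1.0 in 4T1) and Sox4 (-1.84 in 67NR) were lower. Type I interferon response genes lay above 0 in 13 of 13 in 4T1 (median 0.32) and 11 of 13 in 67NR (median 0.49, 0.39 to 0.64). T helper 17 and tissue residence genes did so in 8 of 9 (median 0.40) and 8 of 8 (median 0.57), with S100a6 at 0.92 and 1.14. At Leiden resolution 2 the 4T1 medians of these lists were 0.20 and 0.23, and with cells thinned to 1000 UMIs the former was 0.53.

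**Figure D2:**
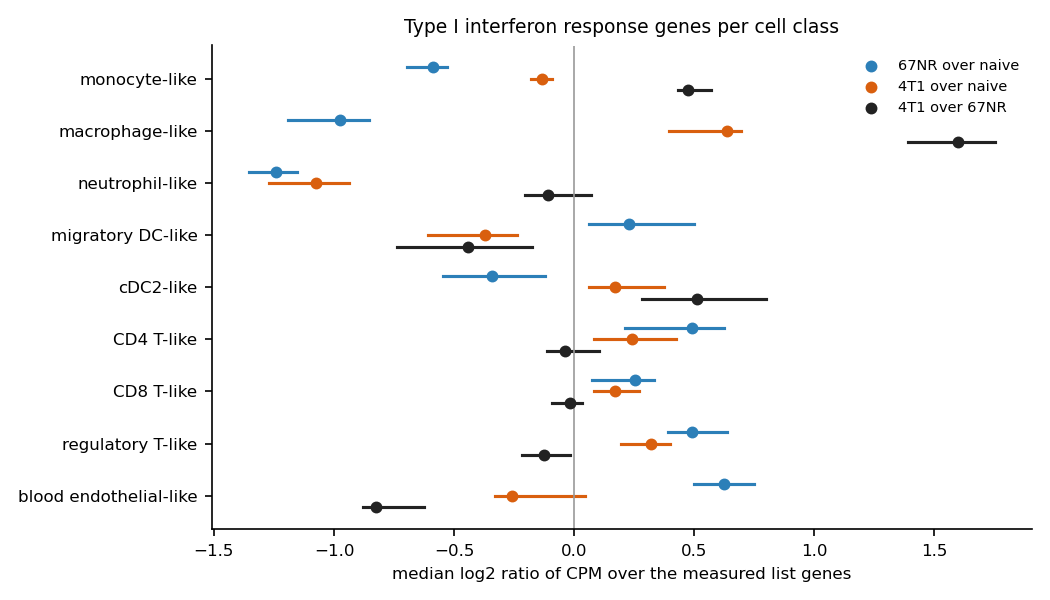
Median log2 ratio of CPM over the measured type I interferon response genes (horizontal axis) in 9 cell classes (vertical axis), for 67NR over naive (blue), 4T1 over naive (orange) and 4T1 over 67NR (black). Points are medians and lines 95% intervals of resampled counts, which cover counting error only, with 1 library behind each class. In 4T1 over 67NR macrophage-like cells lie at 1.60 and blood endothelial-like cells, from the stromal library, at -0.83.

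The naive axillary and mediastinal nodes were compared in the 2 classes named in both atlases. In B-like cells, Il1b was higher in the axillary node by 3.14 (1.77 to 5.03), Uckl1 by 3.55 (1.04 to 8.87) and Ankrd37 by 3.06 (1.18 to 6.12). These rest on 4, 1 and 2 mediastinal UMIs. The T cell genes Rora (-4.07, -4.59 to -3.56) and Camk4 (-3.37, -3.75 to -3.00) were lower. Type I interferon response genes lay above 0 in 9 of 9 (median 0.94, 0.76 to 1.32, Zbp1 at 1.67, Bst2 at 1.27) and MHC class I genes in 10 of 11 (median 0.68). In germinal-centre B-like cells Myzap (4.15, 1.65 to 9.46) and Shcbp1 (3.63) were higher, each on 1 mediastinal UMI. Gzma (-4.63, -5.30 to -3.99) and Ccl5 (-4.26), genes of cytotoxic lymphocytes, were lower. With cells thinned to 1000 UMIs, Uckl1 in B-like cells and Myzap and Shcbp1 in germinal-centre ones had 0 mediastinal UMIs. Interferon-gamma and MHC class II genes lay above 0 in 7 of 8 (median 0.52). Axillary B-like cells held a median of 5036 UMIs against 1307, and germinal-centre B-like cells 11114 against 3075. The axillary sums held 8202747 UMIs against 875190, and 6500054 against 585617. A gene higher in the mediastinal node thus reached the 50 UMIs of a measured gene only at a higher CPM. That rule favours list members higher in the axillary node, so the counts above 0 and the medians lean that way. DESeq2 size factors shifted the log2 ratios by 0.188 and 0.252, and with them the B-like interferon median was 0.75 and the germinal-centre MHC class II one 0.27. The B-like interferon median was 1.61 and the MHC class I one 0.33 with at most 5% mitochondrial UMIs, and the former 1.36 with at least 1000 UMIs per cell. With doublets kept the germinal-centre Gzma ratio was 0.13 (-0.23 to 0.50), and the doublet caller had not worked on the mediastinal atlas.

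Surface antibody counts in the axillary atlas were set against the transcripts of their targets over 8 classes. The gamma-delta T cell receptor antibody had a median count of 100 in gamma-delta T-like cells against 1 in the next class, NK-like cells. IgD had 423 in B-like cells against 16 in regulatory T-like cells, CD103 104 in gamma-delta T-like cells against 10, and NKp46 9 in NK-like cells against 1. CD25 was highest in regulatory T-like cells (22), CD11c in migratory dendritic-like cells (26) and CD4 in CD4 T-like cells (212, against 201 in regulatory T-like cells). Of 24 antibodies, 6 had tied highest medians, and for 13 of the other 18 the class with the highest median also held the highest CPM of the target's transcript. CD8, PD-1, CD127, IgM and MHC class II were the exceptions. MHC class II antibody was highest in migratory dendritic-like cells (588) and H2-Ab1 transcript in B-like cells. No class was CD8 T-like, so the low CD8 counts (highest median 6) compare other classes only. Monocyte-, macrophage- and neutrophil-like cells (48, 40 and 20) were under the 50 that a class needed. Ly6G, CD64, Ly6C and CX3CR1 were among the tied antibodies.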

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

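Chosen only after the result was seen were the free RNA and gene-by-gene tests of fibroblast genes found in 1 library, the split by class of the cluster mix tests of interferon genes, the depth of 4000 UMIs in their depth test, and the values in the clusters led by Ccl19 and Ccl21a and with wide class names. The criteria that picked the list medians given here were chosen then too.

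Gene lists whose 4T1 over 67NR medians had opposite signs in different cell types drew attention. The medians, each with its counting interval, lay outside the range of matched random lists with a size of at least 0.5, and the differences between cell types were not tested. Monocyte-attracting chemokines were at -1.94 (-2.32 to -1.29) in migratory dendritic-like cells, against 1.0 (0.86 to 1.15) in neutrophils, 1.15 (0.94 to 1.42) in monocytes and 1.43 (1.03 to 1.90) in cDC2-like cells. Type I interferon response genes were at -0.83 (-0.88 to -0.63) in blood endothelial cells, against 0.51 (0.28 to 0.80) in cDC2-like cells and 1.60 (1.39 to 1.75) in macrophages. Interferon-gamma and MHC class II genes were at -1.03 (-1.33 to -0.94) in blood endothelial cells and 0.66 (0.56 to 0.81) in neutrophils, and neutrophil-attracting chemokines at -0.77 (-1.01 to -0.55) and 0.93 (0.82 to 1.0). Proliferation genes were at -2.04 (-2.98 to -1.38) in neutrophils and 0.66 (0.42 to 0.91) in T cell cluster 6. Chemokine lists rested on 3 to 8 measured genes, and proliferation in neutrophils on 4. Other settings moved some of these medians by over 1.5 times. With genes of at least 10 UMIs the chemokine median of cDC2-like cells turned to -0.56, that of migratory dendritic-like cells was -1.25 and the neutrophil proliferation one -1.21. The migratory dendritic one was -0.40 with at least 1000 UMIs per cell, -0.39 with at most 5% mitochondrial UMIs and -0.40 with doublets kept. With a hashtag ratio of 10 neutrophil proliferation turned to 0.48, and the interferon medians of macrophages and cDC2-like cells were 0.81 and 0.78. The MHC class II median of neutrophils was 0.34 with cells thinned to 1000 UMIs, under the 0.5 that picked it, and the chemokine one of monocytes 0.76 with at most 5% mitochondrial UMIs.

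By median, collagen and matrix genes were higher in fibroblasts of both tumour conditions, with 23 of 28 above 0 in 4T1 and 25 in 67NR. Most members did not pass over all genes, and camera did not call the list with an estimated correlation. With each fibroblast cluster given the same weight in every condition, at least 95.7% of the median remained as a mean of the 2 libraries. In the stromal library it went from 0.78 to 0.76 in 4T1 and from 0.71 to 0.79 in 67NR, and in the other from 0.40 to 0.37 and from 0.41 to 0.38. With cells thinned to 1000 UMIs at least 103% remained. The equal weights argue against a different mix of the named clusters as the whole source. Random thinning keeps the class names and the expected share of each gene in a cell. It therefore argues only against the weight of cells with many UMIs in the sums, and cannot decide on depth otherwise. In the clusters led by Ccl19 and Ccl21a alone the medians were 0.60 and 0.28, against 0.66 and 0.51, so a part of the mix in 67NR stays open. The mix test leaves out the unnamed stromal cluster led by Smpd3 and Fn1, and wide class names, which add it, gave 0.58 and 0.61. The 2 tests cover no difference of handling or mice, since each condition was 1 hashtagged pool per library, and no free RNA. A response of fibroblasts to tumour growth may lie behind the pattern. That is a hypothesis raised by these data, and it was not tested.

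In fibroblasts 17 genes passed the test with under 10 UMIs per compared condition in the stromal library, among them Csf3, Csf2, Lyz1, Retnlg and Ccr7. The 36 fibroblast droplets with the most UMIs of these genes held 71.2% of them (68.5% without the most abundant gene), above the highest of 1000 simulated even spreads, 14.7% (14.9%). This argues against free RNA of the whole pool as the whole source. Fibroblast droplets with a UMI of the gene ran from 12 of 702 for Csf2 to 244 for Retnlg, so a part from free RNA stays open. The 36 droplets held a median of 32484 UMIs against 16095 in the other 666. Of the genes, 0 stood higher in fibroblasts than in every other cluster, with 0.571 as the highest lower bound of that ratio. Droplets holding a fibroblast and a leukocyte of the same condition, which 1 hashtag cannot reveal, may be the source. For Csf3 this stays open, since over all conditions fibroblasts held 26 CPM of it against 16.1 in macrophages, the highest other class.

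Interferon genes were higher in macrophages and lower in blood endothelial cells of 4T1 than of 67NR nodes. With equal cluster weights 44.1% of the macrophage median remained (from 1.60 to 0.70), so a different mix of macrophage clusters may account for over 50% of it, and 102% of the endothelial one (-0.84), which argues against a mix there. Without the 10% of cells with the highest share of these transcripts at least 113% remained in each class (1.90 and -0.93). A few cells are thus argued against as the whole source. With cells thinned to 4000 UMIs at least 79.6% remained (1.37 and -0.66). This left out 6 and 4 macrophages and 40 and 27 endothelial cells of 4T1 and 67NR. Random thinning argues only against the weight of cells with many UMIs in the sums as the whole source. It keeps the class names and the expected share of each gene in a cell, so it cannot decide on depth otherwise. A difference between the tumours stays open and untested, with 1 library behind each class.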

How the results depend on the processing

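Chosen only after the data were seen were the hashtag ratio of 10, the wide class names, the fibroblast clusters led by Ccl19 and Ccl21a, the count of called genes with 10 UMIs in each library, and every setting of the blood endothelial and LPS comparisons and of the T cell clusters compared by number. Single genes and lists that answer no comparison by themselves numbered 558, with 5025 recomputed values. Of these 4011 stayed, 674 moved, 206 fell short of the threshold and 79 newly passed it, and 55, of 44 results, turned. Of the turned ones, 24 were single genes with a counting interval, which spanned 0 in 20. Among those that stayed or moved, 15 changed sign, of 8 results that lay within their SE or interval of 0. They were medians of the TLR4 list (monocytes, 4T1, and fibroblasts, 67NR), of interferon genes (blood endothelial cells, 4T1) and of stress and damage genes (fibroblasts, 67NR), each over naive, and Ly96 (monocytes, 4T1, and fibroblasts, LPS, over naive) and Tlr4 (macrophages, 4T1 over 67NR). Of further values, which answer a comparison, 133 stayed within their interval or within 1.5 times and 79 moved. Hashtag pools without a condition were not analysed, because the hashtag names give every condition. A further 29 recomputed values of single genes had 0 UMIs in 1 group, nearly all after thinning, and gave only a bound that left their direction or size open, so they count nowhere. The edgeR fit with no replicate block called 0, 0 and 0 genes in the comparisons of 4T1 with naive, 67NR with naive and 4T1 with 67NR, with 437, 406 and 156 at an unadjusted p under 0.05, and edgeR with the block 72, 79 and 3. That fit leaves the level difference between the libraries in its spread. No test was possible without 1 library, since no residual degrees of freedom remain. The calls' signs held for 63, 79 and 1 genes in the stromal library alone and for 72, 79 and 3 in the myeloid and stromal library alone. Both libraries made the calls, so these signs are no separate check. Depth limits genes under 50 UMIs, and the mediastinal atlas, at a median of 2272 UMIs per cell, left 24708 of 25148 cells unnamed.

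DESeq2 called 105, 136 and 1 genes, kept 46 of the 72 calls of 4T1 over naive and 65 of the 79 of 67NR over naive, and gave no adjusted p for 8948 and 6711 genes. Its calls in 4T1 over naive were 83.8% higher, against 68.1% in edgeR. DESeq2 size factors in edgeR kept every call (73, 82 and 3 called). Without a gene filter edgeR called 713, 759 and 182, of which 26, 29 and 13 were genes that the filter removes, and 53.7% and 69.4% of the calls over naive were higher. At Leiden resolution 2 57.8% and 66.1% were higher and with wide class names 57.4% and 65.9%, against 68.1% and 86.1%. With size factors the interferon median of B-like cells, axillary over mediastinal, was 0.75. Of called genes with 10 UMIs in each library, 0 remained in 4T1 over 67NR. In the values that follow, of results that turned or moved, the cause was not tested.

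With at least 1000 UMIs per cell the shares were neutrophil-like cells 33.8% of the myeloid and stromal library, CD4 T-like cells 12.2% of the T cell library and B-like cells 0.388% of the mediastinal atlas. There the fibroblast test called 122 in 67NR over naive and 5 in 4T1 over 67NR. In monocytes the monocyte-attracting chemokines median stood at -1.95 for 67NR over naive. In neutrophils the type I interferon response median stood at -0.63 for 4T1 over naive. In CD4 T-like cells the follicular helper median stood at 1.62 for 4T1 over naive, Xcl1 at 0.47 for 67NR over naive. In B-like cells the type I interferon response median stood at 1.36 for axillary over mediastinal. With at most 5% mitochondrial UMIs the shares were fibroblast-like cells 46.9% and blood endothelial-like cells 27.5% of the stromal library, neutrophil-like cells 34.7% and fibroblast-like cells 11.9% of the myeloid and stromal library, CD8 T-like cells 34.2% and regulatory T-like cells 20.1% of the T cell library, NK-like cells 20.5% of the axillary atlas and B-like cells 0.761% of the mediastinal atlas. There the fibroblast test called 38 in 4T1 over naive and 1 in 4T1 over 67NR. In fibroblasts Tlr4 stood at -0.013 for 67NR over naive. In monocytes Ccl2 stood at 0.24 and the monocyte-attracting chemokines median at -1.90 for 67NR over naive. In macrophages the type I interferon response median stood at 1.37 for 4T1 over 67NR. In neutrophils the type I interferon response median stood at -0.63 for 4T1 over naive. In CD8 T-like cells the T cell activation and effector median stood at 0.26 for 67NR over naive. In B-like cells the type I interferon response median stood at 1.61 for axillary over mediastinal. With doublets kept the shares were neutrophil-like cells 18.8% and fibroblast-like cells 17.1% of the myeloid and stromal library, CD4 T-like cells 11.9% and regulatory T-like cells 25.2% of the T cell library and NK-like cells 18.5% and B-like cells 13.3% of the axillary atlas. In monocytes S100a9 stood at 0.016 for 4T1 over naive, the monocyte-attracting chemokines median at -1.46 for 67NR over naive. In neutrophils the type I interferon response median stood at -1.32 for 4T1 over naive. In CD4 T-like cells Ccl5 stood at 0.88, Itgae at 0.23, S100a4 at 0.58, the follicular helper median at 0.36 and the T helper 17 and tissue residence median at 0.35 for 4T1 over naive, Ccl5 at 1.07, Itgae at 0.22, S100a4 at 0.048, S100a6 at 0.14 and the T helper 17 and tissue residence median at 0.048 for 67NR over naive. In germinal-centre B-like cells Gzma stood at 0.13 for axillary over mediastinal. At Leiden resolution 2 the shares were fibroblast-like cells 55.7% and blood endothelial-like cells 23.8% of the stromal library, neutrophil-like cells 28.4% of the myeloid and stromal library and CD8 T-like cells 21.7%, CD4 T-like cells 19.8% and regulatory T-like cells 24.7% of the T cell library. There the fibroblast test called 135 in 4T1 over naive, 339 in 67NR over naive and 5 in 4T1 over 67NR. In fibroblasts Cxcl12 stood at -0.070 for 67NR over naive. In neutrophils the type I interferon response median stood at -0.78 for 4T1 over naive.

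With cells thinned to 1000 UMIs the fibroblast test called 38 in 4T1 over naive. In fibroblasts Acta2 stood at -0.64 and Tlr4 at -0.25 for 4T1 over naive, Acta2 at -0.16 and Tlr4 at -0.039 for 67NR over naive. In monocytes the alarmins and neutrophil granules median stood at 0.80 for 4T1 over naive, Ccl2 at 0.18 for 67NR over naive, and Ifit3 at -0.12 and Usp18 at -0.015 for 4T1 over 67NR. In macrophages Xaf1 stood at -0.34 for 4T1 over naive. In neutrophils the type I interferon response median stood at -1.56 for 4T1 over naive. In CD8 T-like cells Eomes stood at -0.25 for 67NR over naive. In regulatory T-like cells Ifit1 stood at -0.42 and Wnt10a at 0.11 for 67NR over naive. In blood endothelial cells the type I interferon response median stood at -1.0 for 4T1 over 67NR. With genes of at least 10 UMIs, in cDC2-like cells, the monocyte-attracting chemokines median stood at -0.56 for 4T1 over 67NR. With a hashtag ratio of 10 the shares were fibroblast-like cells 49.2%, blood endothelial-like cells 33.0% and lymphatic endothelial-like cells 8.83% of the stromal library, monocyte-like cells 17.3%, neutrophil-like cells 34.5% and fibroblast-like cells 7.23% of the myeloid and stromal library and CD4 T-like cells 18.3% of the T cell library. There the fibroblast test called 15 in 4T1 over naive, 11 of them among the 72 calls. In fibroblasts Ly96 stood at 0.017 for 4T1 over naive, Tlr4 at -0.33 for 67NR over naive. In monocytes the alarmins and neutrophil granules median stood at 0.61 for 4T1 over naive, Ccl2 at 0.44 for 67NR over naive. In macrophages the type I interferon response median stood at 0.81 for 4T1 over 67NR. In neutrophils Camp stood at 0.075 and the type I interferon response median at -0.78 for 4T1 over naive, the proliferation median at 0.48 for 4T1 over 67NR. In CD4 T-like cells the follicular helper median stood at 1.61 for 4T1 over naive, Ccl5 at 0.070 and Xcl1 at 0.47 for 67NR over naive. With wide class names, where genes of the fixed lists also count as a class's own, the shares were fibroblast-like cells 55.8% of the stromal library and CD8 T-like cells 40.8% of the T cell library. There the fibroblast test called 129 in 4T1 over naive, 340 in 67NR over naive and 5 in 4T1 over 67NR. In fibroblasts Cxcl12 stood at -0.071 for 67NR over naive. In CD8 T-like cells Tbx21 stood at -0.26 for 4T1 over naive, Gzma at -0.97 and the T cell activation and effector median at 0.10 for 67NR over naive. In the fibroblast clusters led by Ccl19 and Ccl21a alone the fibroblast test called 17 in 4T1 over naive, 40 in 67NR over naive and 1 in 4T1 over 67NR. These kept 7 of the 72, 13 of the 79 and 0 of the 3 calls. In fibroblasts Ccl19 stood at -0.50, Il6 at -1.59, Ly96 at 0.73, Tlr4 at -0.0090, the type I interferon response median at 0.45, the homeostatic stromal factors median at -0.11, the dissociation stress and immediate early median at 0.17 and the signs of damaged cells median at -0.010 for 4T1 over naive, Ccl19 at -0.28, Col6a2 at -0.011, Cxcl12 at -0.30, Il34 at -0.33, Il6 at -0.67, Tlr4 at -0.083, the type I interferon response median at 0.40 and the homeostatic stromal factors median at -0.29 for 67NR over naive, and Retnlg at 0.060 and Wfdc17 at -0.53 for 4T1 over 67NR.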

Other observations

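All comparisons of this part were chosen after the hashtag names or the clusters were seen, and they have 1 sum of cells per condition and no test. Ranges are exact 95% intervals that cover counting error only.

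LPS, a ligand of Tlr4, had been injected 72 hours earlier in 1 condition of the stromal library. Its fibroblasts (386 cells, median 17612 UMIs) were set against naive ones (189 cells, 12265). The acute-phase gene Saa3 was higher by a log2 ratio of 8.05 (6.20 to 11.10), on 2 UMIs in naive cells and 1495 in 76 cells after LPS, 32.6% of them in 1 cell. Lcn2, which encodes the iron-carrier-binding protein lipocalin 2, was higher by 4.77 (2.25 to 10.10), on 1 UMI in naive cells, with 33.8% of the LPS ones in 1 cell. The complement gene Cfb was higher by 2.40 (2.21 to 2.59) and Rsad2, an antiviral interferon-induced gene, by 2.83 (1.82 to 4.07). Type I interferon response genes lay above 0 in 17 of 19 (median 0.78, 0.54 to 0.92, Irf7 at 1.98). MHC class I genes did so in 11 of 12 (median 0.44, H2-D1 at 1.26) and collagen and matrix genes in 24 of 27 (median 0.48, Col3a1 at 1.05). The MHC class I median was 0.92 with cells thinned to 1000 UMIs, and with a hashtag ratio of 10 the collagen one was 0.77 and the contractile one -1.22. Contractile genes lay below 0 in 5 of 6 (median -0.79, Acta2 at -1.66, -1.98 to -1.34, Tagln at -1.40). Tlr4 was at 0.06 (-0.21 to 0.35), Ccl2 at 0.33 (0.25 to 0.41). The B cell chemokine gene Cxcl13 was at 1.24 (1.13 to 1.36) and Ccl21a, uncertain for its near-identical copies, at -1.15 (-1.21 to -1.08). Dissociation stress genes lay below 0 in 17 of 18 (median -0.59, Hspa1a at -1.98) and genes of damaged cells in 9 of 10 (median -0.23, -0.37 with a hashtag ratio of 10). The plasma cell transcript Igkc had 138 UMIs against 13 in naive fibroblasts, 71.0% of the former in 1 cell.

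Blood endothelial-like cells of the stromal library numbered 192 in 4T1, 201 in 67NR, 140 after LPS and 169 in naive nodes. In 67NR over naive, interferon-gamma and MHC class II genes lay above 0 in 15 of 15 (median 0.91, 0.78 to 1.10). H2-Eb1 was at 3.09 (2.66 to 3.56), H2-Aa at 2.78 (2.31 to 3.29) and the invariant chain gene Cd74 at 2.03 (1.88 to 2.19). There the type I interferon response genes lay above 0 in 15 of 16 (median 0.63, 0.50 to 0.75). After LPS the same lists lay above 0 in 14 of 14 (median 0.96) and 17 of 17 (median 1.20, Ifit1 at 2.24). Glycam1, a mucin-like gene of high endothelial venules, was lower by a log2 ratio of -2.95 (-3.00 to -2.90). In 4T1 over naive the type I interferon median was -0.26 (6 of 13 above 0), and it turned to 0.051 with doublets kept and to 0.10 with a hashtag ratio of 10. In 4T1 over 67NR the MHC class II and interferon-gamma list lay below 0 in 15 of 15, with H2-Eb1 at -3.45 (-3.90 to -3.04). Dissociation stress genes had a median of -0.51 in 4T1 (-0.32 with cells thinned to 1000 UMIs) and -0.24 in 67NR over naive, and genes of damaged cells 0.31 in 67NR (0.14 with at most 5% mitochondrial UMIs).

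Of the T cells, clusters 6 and 7 stayed unnamed and were compared by number. In cluster 7 type I interferon response genes lay above 0 in 9 of 9 in 4T1 (median 0.63) and 9 of 9 in 67NR over naive (median 0.63). Cxcl10, an interferon-induced chemokine gene, was at 1.37 and 2.52. In cluster 6 (185, 187 and 149 cells of 4T1, 67NR and naive nodes), regulatory T cell genes lay above 0 in 8 of 8 in 4T1 over naive (median 0.35, 0.062 with cells thinned to 1000 UMIs). The costimulatory receptor genes Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB) were at 2.02 (1.43 to 2.65) and 0.97 (0.64 to 1.31) in 4T1 and at 1.98 and 0.84 in 67NR.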
